A study of Mus musculus with 18 samples.

How the data were processed

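The series holds poly(A)+ RNA-seq of the peritumoral area resected around brain metastases in 18 mice, 6 for each of 3 tumour models, taken 10 days after injection of 40000 cells, per the labels' protocols. RNA was isolated with the RNeasy kit and 1 µg went into directional libraries (NEBNext Ultra II, antisense orientation), per the labels' protocols. Reads were demultiplexed with bcl2fastq and the build was GRCm39, per the submitters' processing notes, while aligner, counter, annotation release and strand setting were not given in the sources used here. The deposited count table gives raw counts per versioned mouse Ensembl gene, 1 column per library, with no normalization by the authors, as its whole-number values show. The deposited CPM table gives CPM on an adjusted library size for 16925 genes under upper-case symbols, and the rule by which the genes were chosen was not given in the sources used here. For the 15366 rows matched by symbol, whole reads were recovered from 100% of the CPM values (tolerance 0.01), at least 99.8% of them equal to the counts, with implied scaling factors of 0.968 to 1.06 and column sums of 884780 to 973865.

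Symbols, transcript lengths and chromosomes were taken from GENCODE M21 on GRCm38 by gene ID without its version, and no coordinates were used, as the build differs. Of 55416 gene IDs 52083 (94.0%) had a symbol, holding 99.8% of reads. All 18 deposited libraries and all columns were used. Number 12 of the library numbers was not analysed here, as no file or label holds it. The smallest chi-square per degree of freedom between 2 libraries of a model was 2.82 and no pair was identical, so that no library was a repeat sequencing of another. Totals of 7366250 to 14533877 counts put 3 counts in a library at 0.203 to 0.419 CPM, the floor under which a gene cannot be told from unread in that library.

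Counts were fitted with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood method, with TMM factors, filterByExpr (17174 genes, 99.8% of reads) and 1 coefficient per model over all 18 libraries. The 3 pairwise contrasts and 1 test of any difference among the models were made, with Benjamini-Hochberg adjustment over all genes tested and changes called at an adjusted p under 0.05. A gene was set apart in a model if it was called in the same direction against both others. Values are mean CPM ± SD of 6 libraries on TMM-scaled library sizes. Standard errors are those of the log2 fold change. For a gene with no read in a model a bound was set with a floor of 3 counts over the model, and for 1 to 3 reads a 95% interval of the ratio of read numbers was given.

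In 48 gene lists of cell types, brain regions and processes (581 genes, 539 tested), written down before the data were examined, changes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 144 tests. Each test was repeated with an estimated correlation and with fry, and, chosen after seeing the data, with an exact permutation of list means over all 924 splits of 6 against 6 (smallest p 0.00216). Named genes followed a rule fixed before the data were examined: the 6 largest changes each way among called genes with a mean of at least 1 CPM and no overlap between models, the 3 members with the smallest p per called list, the 5 genes each way with the smallest larger p among those set apart, and 9 genes named in every comparison (Egr1, Fos, Arc, Gfap, Pmel, Krt8, Krt18, Nkx2-1 and Sftpc). Of the 68, 49 and 72 genes the rule named for melanoma against lung, breast against lung and melanoma against breast, a part is described, and some are not reported here. Members that moved against their list, Xist, and the genes of the closing observations were added after their values were seen.

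Alternatives fixed before the data were examined were other scalings (DESeq2 size factors, upper quartile, library totals), filters, tests (DESeq2 1.42.0, limma voom, limma on the deposited CPM), fits of 12 libraries, a test against 1.5-fold, a cell cycle covariate, 1 surrogate variable (sva 3.50.0), and each library left out in turn. Alternatives chosen after seeing the data left out the 3 libraries with a slope of log2 CPM against transcript length under -0.2, removed that trend, or used the reads recovered from CPM. The fit was tested on simulated data. With 200 genes changed by 2-fold, 60.5%, 62.0% and 67.5% were found (4, 2 and 6 false calls), and with 4-fold 93.0%, 95.5% and 95.0% (6, 12 and 11 false calls). In 10 simulations of unchanged models none was called. Genes were drawn independently of each other in these simulations, so variation shared by the genes of a library was absent. The simulated false calls therefore do not bound those in the real libraries.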

Results

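The brain metastasis-associated microenvironment was profiled by bulk RNA-seq of the tissue resected around tumours in 18 mouse brains. Each brain was taken 10 days after injection of 40000 tumour cells. The melanoma model used B16-F10-BrM4 cells, a brain-metastatic derivative of the B16-F10 mouse melanoma line, the lung cancer model used 482N1 cells, and the breast cancer model used EO771-BrM3 cells, a brain-metastatic derivative of the EO771 mouse mammary carcinoma line. There were 6 brains per model, with library numbers 1 to 6 for melanoma, 7 to 11 and 13 for lung, and 14 to 19 for breast. No tumour-free brain was among them, so that every comparison was between models. Melanocyte genes were read in the melanoma libraries and epithelial genes in the lung libraries, so that tumour RNA can be part of any difference. Whether the tumour cells or the tissue around them made the RNA of a gene was not tested. Totals ran from 10669355 to 13396710 counts in the melanoma libraries, from 12070005 to 14533877 in the lung libraries and from 7366250 to 13544054 in the breast libraries, where replicates 18 and 19 were the shallowest with 7366250 and 7432159.

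The models separated on the first principal components, which held 48.6% and 23.5% of the variance of log2 CPM. Melanocyte and epithelial genes marked the models: Pmel, a melanosome structural protein, stood at 2558 ± 1639 CPM (mean ± SD, n = 6) in melanoma against 1.21 ± 0.433 in lung and 1.47 ± 0.614 in breast libraries, and Krt18, a simple-epithelial keratin, at 358 ± 173 CPM in lung against 1.89 ± 0.525 in melanoma and 2.13 ± 0.990 in breast libraries. Melanocyte genes took 0.404% to 2.51% of the reads of the melanoma libraries, 0.00724% to 0.0115% in lung and 0.00170% to 0.00263% in breast. Long transcripts were under-represented in melanoma replicate 3 and breast replicates 18 and 19, where log2 CPM changed by -0.366, -0.346 and -0.284 per doubling of transcript length, against -0.158 to 0.243 in the other 15 libraries. Counts are therefore also given without these 3 libraries, an alternative chosen after seeing the data. In 17174 genes tested, 6146 (35.8%) differed among the 3 models, and 8373 without these 3 libraries.

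**Figure D1:**
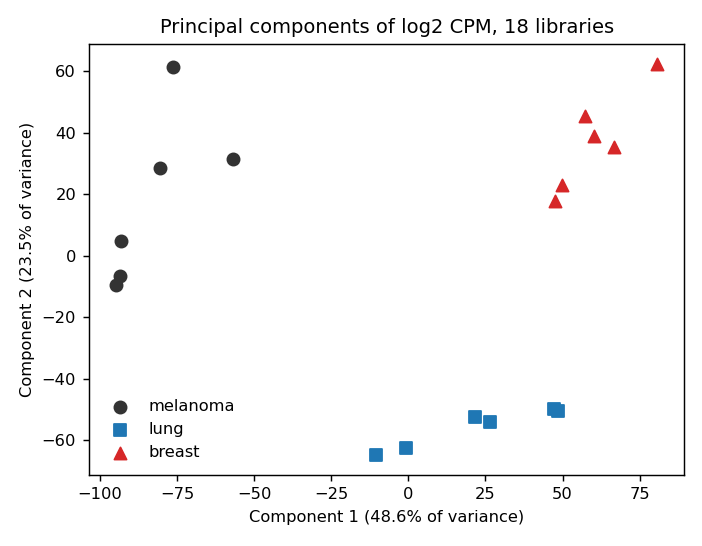
Principal components of log2 CPM in 18 libraries, with 1 point per brain, component 1 (48.6% of the variance) on the horizontal axis and component 2 (23.5%) on the vertical axis. The 6 melanoma libraries lie at -94.8 to -56.8 on component 1 and the lung and breast libraries at -10.6 to 80.7, with lung below breast on component 2.

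**Figure D2:**
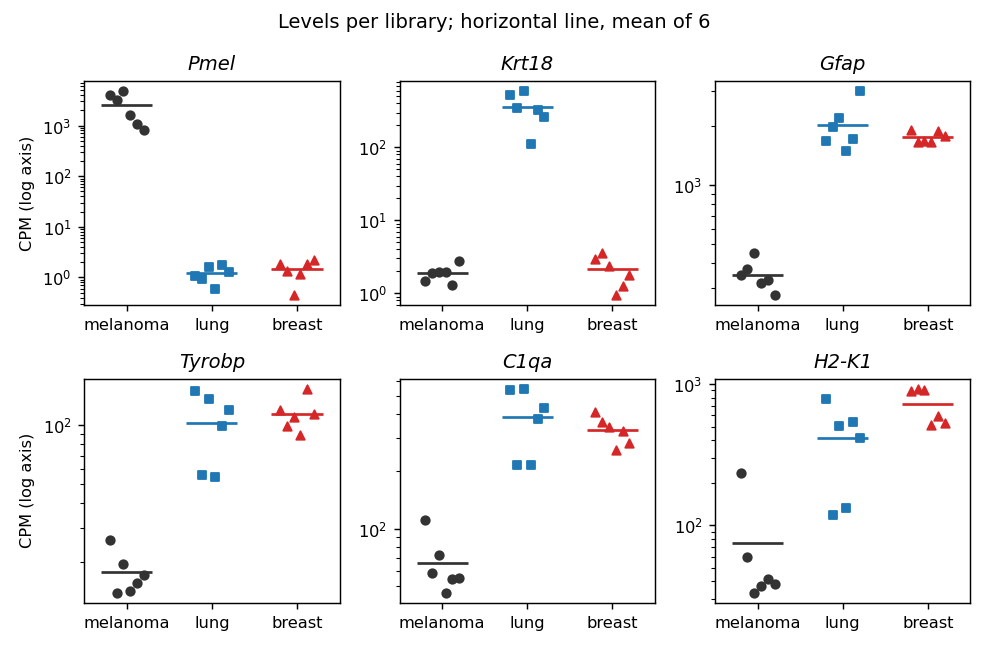
CPM of Pmel, Krt18, Gfap, Tyrobp, C1qa and H2-K1 in each library on a log axis, by model, with 1 point per brain and a line at the mean of 6. Pmel is at 2558 CPM in the melanoma model and Krt18 at 358 CPM in the lung model, while Gfap averages 349 CPM in melanoma against 2013 in lung and 1765 in breast.

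Libraries from around melanoma had lower expression of reactive astrocyte, microglial, complement and cytokine genes than those from around lung tumours. Gfap, the intermediate filament of reactive astrocytes, was at 349 ± 59.2 against 2013 ± 547 CPM (log2 fold change -2.53 ± 0.16 (SE), adjusted p = 6.78e-10). Serpina3n, an acute-phase serpin of reactive astrocytes, was at 25.8 ± 4.46 against 308 ± 97.2 CPM (log2 fold change -3.58 ± 0.23 (SE), adjusted p = 9.54e-10). C1qa, a subunit of the complement initiator C1q, was at 66.1 ± 23.6 against 387 ± 147 CPM (log2 fold change -2.55 ± 0.26 (SE), adjusted p = 3.91e-07). Trem2, a lipid-sensing microglial receptor, was at 14.6 ± 2.14 against 57.2 ± 12.5 CPM (log2 fold change -1.96 ± 0.16 (SE), adjusted p = 1.42e-08). Fold changes are log2 of the first-named model over the second throughout. Ptgs2, the inducible cyclooxygenase, was at 8.61 ± 3.30 against 183 ± 36.7 CPM (log2 fold change -4.41 ± 0.24 (SE), adjusted p = 9.83e-11). Postn, the matrix protein periostin, was at 3.87 ± 0.865 against 79.5 ± 25.7 CPM (log2 fold change -4.36 ± 0.21 (SE), adjusted p = 2.51e-11). In breast libraries Postn was at 2.91 to 3.55 CPM, so its low level was not particular to melanoma.

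By gene list, of the reactive astrocyte genes 15 of 18 fell (15 adjusted over the list alone, camera adjusted p = 3.27e-11, adjusted p = 0.126 with an estimated correlation). Members not counted as risen or fallen did not pass the test, here and for every other list. Of the homeostatic microglia genes 9 of 10 fell (10 adjusted over the list alone, camera adjusted p = 5.37e-08, adjusted p = 0.183 with an estimated correlation). Olfml3, a secreted olfactomedin-like protein, had a log2 fold change of -1.96. Of the disease-associated microglia genes 13 of 16 fell and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 6.95e-08, adjusted p = 0.165 with an estimated correlation). The member that rose was Gpnmb (log2 fold change 5.23 ± 0.53 (SE), adjusted p = 3.27e-07), a transmembrane protein of melanosomes as well as of activated macrophages. Of the monocyte and border macrophage genes 9 of 12 fell and 2 rose (9 and 2 adjusted over the list alone, camera adjusted p = 5.93e-04, adjusted p = 0.222 with an estimated correlation). S100a4, a calcium-binding protein, had a log2 fold change of -5.74 and Mrc1, the mannose receptor, of -2.29. The members that rose were Itga4 (1.42), the integrin alpha-4 chain, and Lyve1 (0.93), a hyaluronan receptor of lymphatic vessels and perivascular macrophages. Of the neutrophil genes 8 of 9 fell (8 adjusted over the list alone, camera adjusted p = 3.42e-05, adjusted p = 0.305 with an estimated correlation). Of the complement genes 10 of 11 fell (10 adjusted over the list alone, camera adjusted p = 1.96e-07, adjusted p = 0.220 with an estimated correlation). Of the cytokine and NF-kB genes 16 of 16 fell (16 adjusted over the list alone, camera adjusted p = 4.50e-10, adjusted p = 0.222 with an estimated correlation). They included Il1b (-6.32), the interleukin-1 beta gene, and Icam1 (-2.86), a leukocyte adhesion molecule.

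Part of the interferon-response and antigen-presentation genes were also lower. Of the type I interferon response genes 9 of 20 fell (12 adjusted over the list alone, camera adjusted p = 5.92e-06, adjusted p = 0.758 with an estimated correlation). Irf7, the transcription factor that amplifies interferon expression, was at 16.1 ± 15.9 against 108 ± 65.1 CPM (log2 fold change -2.74 ± 0.55 (SE), adjusted p = 8.65e-04). Of the interferon gamma response genes 9 of 15 fell (13 adjusted over the list alone, camera adjusted p = 1.48e-04, adjusted p = 0.758 with an estimated correlation). Gbp5, a guanylate-binding protein gene, had a log2 fold change of -3.14. Of the MHC class I presentation genes 5 of 12 fell (6 adjusted over the list alone, camera adjusted p = 5.82e-04, adjusted p = 0.778 with an estimated correlation). H2-K1, a classical class I heavy chain, was at 74.3 ± 79.3 against 415 ± 257 CPM (log2 fold change -2.48 ± 0.53 (SE), adjusted p = 0.00149). In melanoma replicate 1 H2-K1 was at 235 CPM, against 33.3 to 60 in the other 5. Of the MHC class II genes 1 of 7 fell (4 adjusted over the list alone, camera adjusted p = 0.00290, adjusted p = 0.758 with an estimated correlation). That member was H2-DMa, a peptide-exchange chaperone (log2 fold change -1.72 ± 0.45 (SE), adjusted p = 0.00785). Of the T and NK cell genes 5 of 20 fell (5 adjusted over the list alone, camera adjusted p = 0.00392, adjusted p = 0.808 with an estimated correlation). Lag3, an inhibitory receptor also read in brain tissue, had a log2 fold change of -1.86. Single libraries stood apart in these lists. The mean log2 CPM of the MHC class II list was 6.36 in melanoma replicate 1 against 1.45 to 1.96 in the other 5 melanoma libraries, and 4.15 and 3.88 in lung replicates 8 and 10 against 5.51 to 7.44 in the other 4 lung libraries. The T and NK cell list had the same outlying libraries, at 1.54 in melanoma replicate 1 and -0.576 and -0.822 in lung replicates 8 and 10.

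Among the genes named for the largest changes, the rises were of Slc45a2, Tyrp1, Dct, Tspan10, Pmel and Tyr. The falls included Dynap, Ifi202b, Rps13-ps1, Hnf4a and Apob. Slc45a2, a melanosomal transporter, had 3 reads in the 6 lung libraries and 38981 in the 6 melanoma libraries, a ratio of 13842 (95% counting interval 4737 to 67122). Of the melanocyte lineage genes 12 of 13 rose (12 adjusted over the list alone, camera adjusted p = 1.24e-25, adjusted p = 0.0642 with an estimated correlation). Of the epithelial genes 9 of 9 fell (9 adjusted over the list alone, camera adjusted p = 2.59e-12, adjusted p = 0.0642 with an estimated correlation). Dynap, a transmembrane protein gene, was read at 283 ± 53.6 CPM in lung libraries, with 2 reads in the melanoma libraries (ratio 10338, interval 2862 to 85368). Ifi202b, an interferon-inducible gene, had 1 read in the melanoma libraries (ratio 5345, interval 959 to 211116). Rps13-ps1, a ribosomal pseudogene, had 1 (ratio 3843, interval 689.8 to 151793). Ifi202b also had at most 1 read in each breast library, against 452 to 1637 in each lung library. It thus did not follow the type I interferon list, whose mean was 6.62 log2 CPM in breast and 5.22 in lung. Hnf4a, a transcription factor of liver and gut epithelium, had no read in the melanoma libraries and was at least 547-fold lower than in lung (22.2 ± 8.55 CPM). Such bounds set an unread gene at a floor of 3 counts over the 6 libraries of a model, and bounds and intervals cover counting error only. Of the cell cycle genes 5 of 20 rose (10 adjusted over the list alone, camera adjusted p = 0.00281, adjusted p = 0.873 with an estimated correlation). Mcm2, a replicative helicase subunit, was at 162 ± 92.6 against 46.9 ± 13.2 CPM (log2 fold change 1.79 ± 0.33 (SE), adjusted p = 3.42e-04). The mean of the cell cycle list varied within the melanoma model, from 4.35 in replicate 6, where melanocyte genes took 0.404% of reads, to 6.51 in replicate 1, where they took 1.71%.

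Of the fibroblast and collagen matrix genes 12 of 15 fell and 1 rose (13 and 1 adjusted over the list alone, camera adjusted p = 5.48e-08, adjusted p = 0.0642 with an estimated correlation). Col6a1 had a log2 fold change of -2.84, and the member that rose was Fbln1, the matrix protein fibulin-1 (log2 fold change 1.23 ± 0.22 (SE), adjusted p = 3.44e-04). Of the perineuronal net genes 3 of 10 fell (3 adjusted over the list alone, camera adjusted p = 0.0411, adjusted p = 0.758 with an estimated correlation). These were Has2 (-7.50), a hyaluronan synthase, and Acan (-2.89) and Vcan (-1.64), the proteoglycans aggrecan and versican, all 3 of which tumour and stromal cells can also make. Of the cholesterol synthesis genes 6 of 14 rose (6 adjusted over the list alone, camera adjusted p = 0.00252, adjusted p = 0.758 with an estimated correlation). Dhcr7, the last enzyme of the pathway, was at 77.7 ± 24.5 against 35.6 ± 3.15 CPM (log2 fold change 1.13 ± 0.16 (SE), adjusted p = 2.25e-05). Within the melanoma model the mean of this list was 6.81, 6.61 and 6.43 in replicates 1 to 3, where melanocyte genes took 1.71%, 1.54% and 2.51% of reads, and 6.32, 6.01 and 5.85 in replicates 4 to 6, where they took 0.807%, 0.502% and 0.404%. The lung libraries had 5.83 to 6.10. The slope with transcript length was also higher in melanoma replicates 4 to 6 (0.234 to 0.243) than in 1 to 3 (-0.366 to 0.0748). Fos, an activity-induced transcription factor, was lower (log2 fold change -1.19 ± 0.27 (SE), adjusted p = 0.00238), whereas Egr1 (log2 fold change -0.19 ± 0.37 (SE), adjusted p = 0.784) and Arc (log2 fold change -0.49 ± 0.49 (SE), adjusted p = 0.556) did not pass, nor did Nkx2-1 (0.19, adjusted p = 0.793) and Sftpc (0.74, adjusted p = 0.115), a transcription factor and a surfactant protein of lung epithelium.

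By edgeR's quasi-likelihood test, 3978 of 17174 genes changed, 1461 higher and 2517 lower in melanoma, 2099 of them by over 2-fold. The CPM of the 6 melanoma and 6 lung libraries did not overlap for 2458 genes (14.3%), against 0.216% by chance. Without the 3 libraries poor in long transcripts 5845 genes changed, 3822 of the 3978 among them. Of 48 lists 18 passed camera (19 without those 3 libraries), and 12 of the 18 also passed an exact permutation test of their means. The 6 that did not were the cell cycle, T and NK cell, MHC class I, type I interferon, interferon gamma and cholesterol synthesis lists (adjusted p = 0.290, 0.0723, 0.0544, 0.0544, 0.0511 and 0.0688). None passed with an estimated correlation (camera, lowest adjusted p = 0.0642, 10 lists under an unadjusted p of 0.05), while fry called 23. The cell cycle and perineuronal net calls ended without the 3 libraries (camera adjusted p = 0.0540 and 0.0995), and the perineuronal net call also without melanoma replicate 1 or 3 or lung replicate 8 or 10 (range over the 18 left-out fits 0.013 to 0.0858). With the cell cycle covariate the perineuronal net and cholesterol synthesis calls ended (0.313 and 0.0740).

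**Figure D3:**
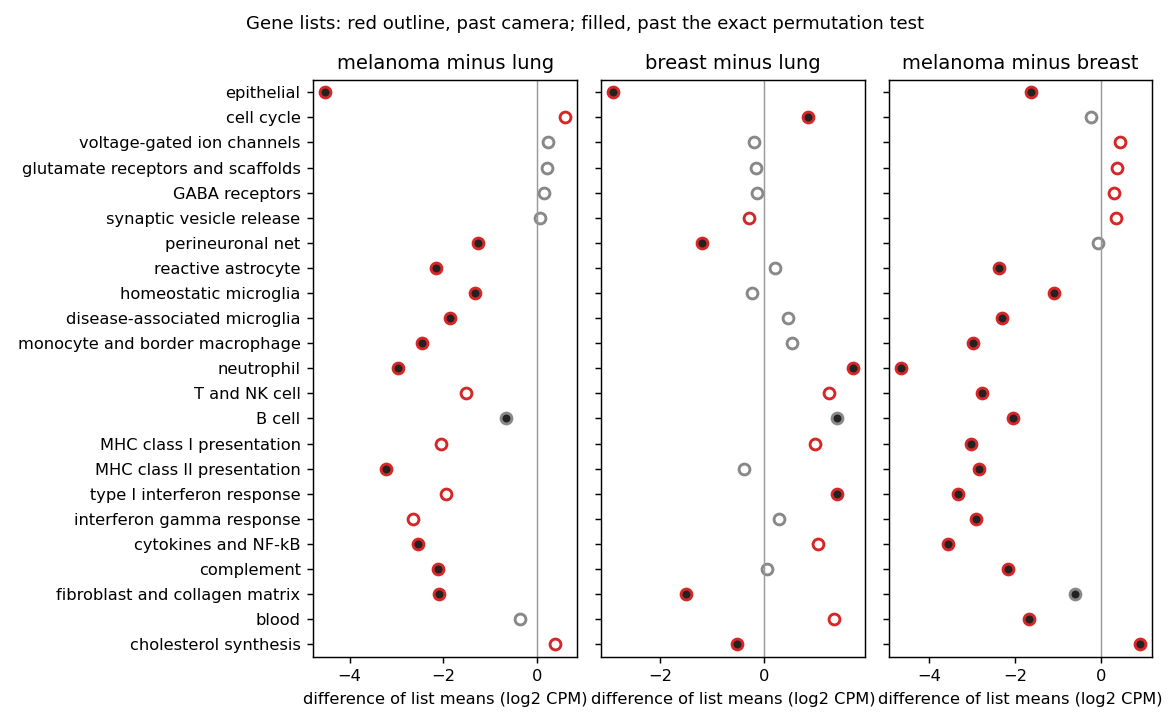
Difference of mean log2 CPM for 23 of the 48 gene lists in the 3 comparisons, on a linear axis, with 1 circle per list, a red outline where camera passed and a filled circle where the exact permutation test passed. Reactive astrocyte and immune lists lie left of 0 in both comparisons of melanoma.

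**Figure D4:**
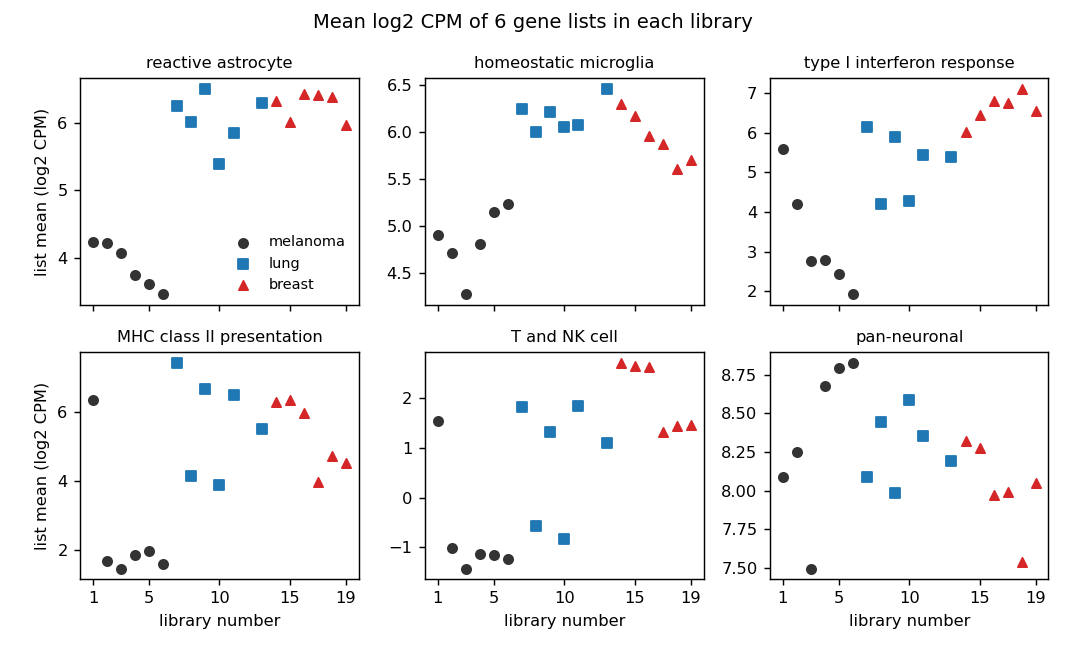
Mean log2 CPM of 6 gene lists in each of 18 libraries, by library number and model, with 1 point per brain. Reactive astrocyte and homeostatic microglia means of every melanoma library lie below those of every lung and breast library, while melanoma replicate 1 and lung replicates 8 and 10 stand apart from their models in MHC class II presentation.

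Among the genes that differed between the breast and lung libraries were interferon-induced, NF-kB and matrix genes. Rsad2, an antiviral interferon-induced protein, was at 173 ± 76.7 against 20.4 ± 7.83 CPM (log2 fold change 3.09 ± 0.61 (SE), adjusted p = 0.00106). Nfkbia, the NF-kB inhibitor that NF-kB itself induces, was at 140.1 ± 34.3 against 45.7 ± 13.4 CPM (log2 fold change 1.61 ± 0.21 (SE), adjusted p = 1.28e-05). Fn1, the matrix protein fibronectin, was at 102 ± 56.0 against 1532 ± 553 CPM (log2 fold change -3.91 ± 0.41 (SE), adjusted p = 8.57e-07). Tex19.1, a germline gene, was read at 41.3 ± 15.3 CPM in breast and not in lung libraries, at least 1009-fold higher. Gfap did not pass, with 1765 ± 118 against 2013 ± 547 CPM (log2 fold change -0.19 ± 0.15 (SE), adjusted p = 0.448).

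Among immune lists, of the type I interferon response genes 5 of 20 rose (11 adjusted over the list alone, camera adjusted p = 4.34e-05, adjusted p = 0.795 with an estimated correlation). Ifi44 had a log2 fold change of 2.42. Of the cytokine and NF-kB genes 6 of 16 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00874, adjusted p = 0.80 with an estimated correlation). Nfkb2, a subunit of NF-kB, rose (1.47), as did the neutrophil chemokine Cxcl2 (3.44), and the member that fell was Ptgs2, the inducible cyclooxygenase (-3.06). With the cell cycle list as a covariate Cxcl2 had a log2 fold change of 1.47 (adjusted p = 0.213). Ifi44 had a log2 fold change of 1.24 (adjusted p = 0.0632), which ended both calls. Of the neutrophil genes 2 of 9 rose (4 adjusted over the list alone, camera adjusted p = 6.65e-04, adjusted p = 0.498 with an estimated correlation). Ly6g, a neutrophil surface marker, had 144 reads in breast and 2 in lung libraries (ratio 83.9, 95% counting interval 23.2 to 693). Csf3r and Cxcr2, of the same list, overlapped between the models. Csf3r was at 15.7 to 64.1 CPM in lung and 21.4 to 53.3 in breast libraries, and Cxcr2 at 0.913 to 24.6 and 9.28 to 18.1. In lung replicate 7 Cxcr2 had 319 reads and Csf3r 830, while Ly6g had 1. Of the T and NK cell genes 3 of 20 rose (3 adjusted over the list alone, camera adjusted p = 0.00290, adjusted p = 0.803 with an estimated correlation). The list mean was 2.61 to 2.70 in breast replicates 14 to 16 and 1.31 to 1.46 in 17 to 19. It was 1.10 to 1.83 in lung replicates 7, 9, 11 and 13, and -0.576 and -0.822 in lung replicates 8 and 10. Pdcd1, an inhibitory T cell receptor, was at 12.4 ± 4.27 against 1.43 ± 1.06 CPM (log2 fold change 3.10 ± 0.57 (SE), adjusted p = 5.56e-04). Within the breast model Pdcd1 did not fall with the list mean. It was at 8.5 to 10.9 CPM in replicates 14 to 16 and 10.8 to 19.996 in 17 to 19. The T cell gene Cd8a was at 7.71 to 8.24 and 0.394 to 0.979 CPM in these libraries. Whether cells other than T cells made part of the Pdcd1 RNA was not tested. Lck, a T cell kinase, had a log2 fold change of 1.13. With the cell cycle covariate Lck did not pass (0.68, adjusted p = 0.202). The MHC class I list passed camera as higher, although 0 of 12 rose (0 adjusted over the list alone, camera adjusted p = 0.0490, adjusted p = 0.878 with an estimated correlation). By edgeR 1 of these 12 members was higher at an unadjusted p under 0.05, while DESeq2 called 1 and limma voom 1. These immune lists moved with lung replicates 8 and 10, whose means lay below those of the other 4 lung libraries in the MHC class I list (5.06 and 5.12 against 6.83 to 8.05) and in the type I interferon list (4.2 and 4.29 against 5.38 to 6.15). Lung replicates 8 and 10 also had the highest slopes with transcript length in their model (0.146 and 0.196, others -0.158 to -0.0088).

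Of the fibroblast and collagen matrix genes 9 of 15 fell and 2 rose (10 and 2 adjusted over the list alone, camera adjusted p = 8.53e-06, adjusted p = 0.126 with an estimated correlation). Postn had a log2 fold change of -4.57 and Col6a1 of -2.26. The members that rose were Col4a1 (0.85) and Col4a2 (0.66), the chains of basement-membrane collagen IV. Of the perineuronal net genes 2 of 10 fell (2 adjusted over the list alone, camera adjusted p = 0.00201, adjusted p = 0.469 with an estimated correlation). These were Has2 (-5.65), the hyaluronan synthase, and Acan (-3.44). Of the cholesterol synthesis genes 7 of 14 fell (10 adjusted over the list alone, camera adjusted p = 4.48e-05, adjusted p = 0.505 with an estimated correlation). Sqle, squalene epoxidase, was at 71.8 ± 5.05 against 118 ± 7.28 CPM (log2 fold change -0.71 ± 0.14 (SE), adjusted p = 0.00129), and with a log2 fold change of -0.69 for Fdft1. Of the synaptic vesicle release genes 1 of 16 fell (0 adjusted over the list alone, camera adjusted p = 0.0318, adjusted p = 0.878 with an estimated correlation). That gene was Syn2, a synapsin (log2 fold change -0.58 ± 0.17 (SE), adjusted p = 0.0235). With the cell cycle covariate the list turned direction (camera adjusted p = 0.647) and Syn2 did not pass (-0.24, adjusted p = 0.195). Of the haemoglobin and erythroid genes 5 of 5 rose (5 adjusted over the list alone, camera adjusted p = 0.0103, adjusted p = 0.733 with an estimated correlation). Hbb-bs, a beta-globin gene whose reads can be shared with its near-identical neighbour, had a log2 fold change of 1.41. Without the 3 libraries poor in long transcripts Hbb-bs had a log2 fold change of 0.81 (adjusted p = 0.198), and it did not pass in 12 other alternatives (adjusted p 0.05 to 0.163). Breast replicates 18 and 19, with few long transcripts, had means of 6.04 and 6.44 in this list, and replicate 14 had 6.29, against 4.89 to 5.19 in the other 3.

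Epithelial, cell cycle and sex-linked genes differed as well. Of the epithelial genes 7 of 9 fell (7 adjusted over the list alone, camera adjusted p = 2.70e-08, adjusted p = 0.105 with an estimated correlation). Krt18 was at 2.13 ± 0.990 against 358 ± 173 CPM (-7.35), while Krt8, its usual partner keratin, was at 100.3 ± 37.9 against 292 ± 136 CPM (log2 fold change -1.54 ± 0.32 (SE), adjusted p = 0.00171). Of the genes with the largest rises, Tex13b was at least 729-fold higher in breast, Dppa4, a pluripotency factor, at least 462-fold, and Mmp1a, an interstitial collagenase, at least 515-fold, with no read of any in lung libraries. Of the cell cycle genes 5 of 20 rose (7 adjusted over the list alone, camera adjusted p = 4.03e-04, adjusted p = 0.803 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, was at 104 ± 19.2 against 38.1 ± 12.1 CPM (log2 fold change 1.45 ± 0.37 (SE), adjusted p = 0.00929). Of the sex-linked genes 4 of 5 fell and 1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 2.56e-09, adjusted p = 0.0642 with an estimated correlation). The Y-linked Ddx3y had no read in the breast libraries and was at least 1214-fold lower than in lung (54.9 ± 7.79 CPM), and the member that rose was Xist, the RNA of the inactive X chromosome, at 104 ± 39.5 against 0.0666 ± 0.133 CPM (10.44). With the 4 unread genes at their bounds the median of this list was -8.89 in place of -11.0. Egr1 (-0.31), Fos (-0.15), Arc (-0.17), Nkx2-1 (-0.20) and Sftpc (0.12) did not pass.

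In all, 3149 genes changed, 1920 higher and 1229 lower in breast, 1347 by over 2-fold, and 2551 (14.9%) showed no overlap between the 6 and 6 libraries (0.216% by chance). Without the 3 libraries poor in long transcripts 4357 changed, 2815 of the 3149 among them, and the share of higher genes went from 61.0% to 46.8%. Camera passed 13 of 48 lists (10 without those libraries), 8 of which also passed the exact permutation test. The 5 that did not were the vesicle release, T and NK cell, MHC class I, cytokine and haemoglobin lists (adjusted p = 0.208, 0.119, 0.198, 0.0661 and 0.0584). With an estimated correlation camera passed none (3 lists under an unadjusted p of 0.05), and fry passed 13. Sex could not be separated from the breast model, and 23.6% of 640 X-linked genes changed, against 18.3% of all genes and 20.2% of X-linked genes in melanoma against lung. The vesicle release, MHC class I and haemoglobin calls ended without the 3 libraries (camera adjusted p = 0.207, 0.0619 and 0.0766). With 1 library left out in turn, the vesicle release call ended in 3 of 18 fits (range of adjusted p 0.0155 to 0.139) and the MHC class I call in 8 (0.00862 to 0.181). With the cell cycle covariate the type I interferon, cytokine, T and NK cell, MHC class I and perineuronal net calls ended (camera adjusted p = 0.137, 0.165, 0.0727, 0.729 and 0.115). As the covariate did not overlap between breast and lung libraries, this does not show that the cell cycle accounts for these calls.

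Between the melanoma and breast models, reactive astrocyte, microglial, type I interferon and MHC class I genes were lower and cholesterol synthesis genes higher around melanoma. H2-D1, a class I heavy chain, was at 172 ± 212 against 1614 ± 239 CPM (log2 fold change -3.23 ± 0.58 (SE), adjusted p = 2.15e-04). Irf7 was at 16.1 ± 15.9 against 276 ± 71.5 CPM (log2 fold change -4.09 ± 0.58 (SE), adjusted p = 1.80e-05). In melanoma replicate 1 H2-D1 was at 603 CPM, against 61.6 to 112 in the other 5 melanoma libraries. Gfap was at 349 ± 59.2 against 1765 ± 118 CPM (log2 fold change -2.34 ± 0.16 (SE), adjusted p = 2.00e-09). Tyrobp, the signalling adaptor of microglial receptors, was at 17.8 ± 4.45 against 114 ± 22 CPM (log2 fold change -2.68 ± 0.25 (SE), adjusted p = 1.13e-07). Sqle was at 169 ± 46.3 against 71.8 ± 5.05 CPM (log2 fold change 1.24 ± 0.14 (SE), adjusted p = 1.83e-06). It ran from 233 CPM in melanoma replicate 1, with 1.71% melanocyte reads, to 115 in replicate 6, with 0.404%.

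Of the type I interferon response genes 19 of 20 fell (20 adjusted over the list alone, camera adjusted p = 3.82e-10, adjusted p = 0.505 with an estimated correlation). Ifi44 had a log2 fold change of -4.71. Of the interferon gamma response genes 7 of 15 fell (7 adjusted over the list alone, camera adjusted p = 4.01e-04, adjusted p = 0.778 with an estimated correlation). Nos2, the inducible nitric oxide synthase, had a log2 fold change of -3.81. Of the MHC class I presentation genes 9 of 12 fell (12 adjusted over the list alone, camera adjusted p = 1.98e-05, adjusted p = 0.697 with an estimated correlation). H2-K1 had a log2 fold change of -3.29. The MHC class II list passed camera as lower, although 0 of 7 fell (0 adjusted over the list alone, camera adjusted p = 0.0234, adjusted p = 0.803 with an estimated correlation). By edgeR 2 of its members were lower at an unadjusted p under 0.05, while DESeq2 called 0 and limma voom 6. In melanoma replicate 1 these 4 lists had means of 5.59, 5.47, 7.24 and 6.36 log2 CPM, against highest means of 4.21, 3.09, 4.67 and 1.96 in the other 5 melanoma libraries. In the MHC class II list breast replicates 17 to 19 had means of 3.95 to 4.71 against 5.98 to 6.35 in breast replicates 14 to 16, all below melanoma replicate 1. Of the T and NK cell genes 16 of 20 fell (19 adjusted over the list alone, camera adjusted p = 2.65e-06, adjusted p = 0.670 with an estimated correlation). Pdcd1 was at 0.670 ± 1.08 against 12.4 ± 4.27 CPM (log2 fold change -4.11 ± 0.62 (SE), adjusted p = 3.43e-05). In melanoma replicate 1 Pdcd1 was at 2.87 CPM, against 0.0929 to 0.313 in the other 5. Within the breast model Pdcd1 was not lower in replicates 17 to 19, unlike the T and NK cell list. The mean of this list was 2.61 to 2.70 in breast replicates 14 to 16 and 1.31 to 1.46 in 17 to 19, against 1.54 in melanoma replicate 1 and -1.42 to -1.0 in the other 5 melanoma libraries. Of the B cell genes 4 of 4 fell (4 adjusted over the list alone, camera adjusted p = 0.0113, adjusted p = 0.285 with an estimated correlation). Pax5, a B-lineage transcription factor, was at 0.603 ± 0.279 against 16 ± 6.67 CPM (log2 fold change -4.72 ± 0.33 (SE), adjusted p = 3.26e-09).

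Of the reactive astrocyte genes 15 of 18 fell (16 adjusted over the list alone, camera adjusted p = 8.64e-11, adjusted p = 0.131 with an estimated correlation). Emp1, an epithelial membrane protein, had a log2 fold change of -4.72. Of the homeostatic microglia genes 8 of 10 fell (8 adjusted over the list alone, camera adjusted p = 4.32e-05, adjusted p = 0.359 with an estimated correlation). Olfml3 had a log2 fold change of -1.88. Of the disease-associated microglia genes 14 of 16 fell and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 1.04e-07, adjusted p = 0.165 with an estimated correlation). Trem2 had a log2 fold change of -2.00, and the member that rose was Gpnmb (3.64), which melanosomes also carry. Of the monocyte and border macrophage genes 9 of 12 fell and 1 rose (9 and 1 adjusted over the list alone, camera adjusted p = 2.22e-04, adjusted p = 0.190 with an estimated correlation). Itga4, the integrin chain, rose (1.16). Of the neutrophil genes 9 of 9 fell (9 adjusted over the list alone, camera adjusted p = 4.85e-08, adjusted p = 0.165 with an estimated correlation). Csf3r, the granulocyte colony-stimulating factor receptor, was at 5.21 ± 1.52 against 38.0 ± 12.6 CPM (log2 fold change -2.87 ± 0.34 (SE), adjusted p = 1.88e-06). Of the complement genes 10 of 11 fell (10 adjusted over the list alone, camera adjusted p = 2.87e-06, adjusted p = 0.278 with an estimated correlation). C1qc had a log2 fold change of -2.37. Of the cytokine and NF-kB genes 16 of 16 fell (16 adjusted over the list alone, camera adjusted p = 3.27e-11, adjusted p = 0.190 with an estimated correlation). Nfkbia was at 20.8 ± 5.44 against 140.1 ± 34.3 CPM (log2 fold change -2.75 ± 0.22 (SE), adjusted p = 1.58e-08). Of the haemoglobin and erythroid genes 5 of 5 fell (5 adjusted over the list alone, camera adjusted p = 0.0208, adjusted p = 0.758 with an estimated correlation). The mean of this list was 6.04 and 6.44 in breast replicates 18 and 19, poor in long transcripts, and 6.29 in replicate 14. Breast replicates 15 to 17 had 4.89 to 5.19, and the call ended without the 3 libraries poor in long transcripts (camera adjusted p = 0.0770).

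Of the cholesterol synthesis genes 13 of 14 rose (14 adjusted over the list alone, camera adjusted p = 1.45e-08, adjusted p = 0.230 with an estimated correlation). Dhcr7 had a log2 fold change of 1.27 and Fdft1, squalene synthase, of 0.79. The list mean was 6.43 to 6.81 in melanoma replicates 1 to 3 and 5.85 to 6.32 in replicates 4 to 6, where melanocyte genes took fewer reads, against 5.34 to 5.49 in the breast libraries. Melanoma replicates 4 to 6 also had higher slopes with transcript length (0.234 to 0.243) than replicates 1 to 3 (-0.366 to 0.0748). The 4 neuronal lists passed camera with few members past the gene test, and none of the 4 passed fry (adjusted p = 0.336, 0.271, 0.170 and 0.191 in the order given) or exact permutation (0.403, 0.408, 0.219 and 0.322). Of the voltage-gated ion channel genes 1 of 26 rose (0 adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.893 with an estimated correlation). Of the glutamate receptor and scaffold genes 1 of 18 rose (1 adjusted over the list alone, camera adjusted p = 0.0230, adjusted p = 0.878 with an estimated correlation). It was Grik2, a kainate receptor subunit (log2 fold change 0.49 ± 0.13 (SE), adjusted p = 0.00678). With the trend with transcript length removed Grik2 did not pass (0.31, adjusted p = 0.182). Of the GABA receptor genes 1 of 14 rose (1 adjusted over the list alone, camera adjusted p = 0.0446, adjusted p = 0.876 with an estimated correlation). It was Gabra5 (log2 fold change 0.48 ± 0.14 (SE), adjusted p = 0.0125). Of the synaptic vesicle release genes 2 of 16 rose (0 adjusted over the list alone, camera adjusted p = 0.0141, adjusted p = 0.878 with an estimated correlation). They were Snap25, a membrane-fusion SNARE protein (log2 fold change 0.39 ± 0.13 (SE), adjusted p = 0.0325), and Sv2b (0.49). Snap25 did not pass with 1 surrogate variable (adjusted p = 0.0704), in the fit of 12 libraries (0.0839) or without breast replicate 16 (0.0702). Within their models all 4 lists were lowest in melanoma replicate 3 and breast replicate 18, which were poor in long transcripts. The mean of the ion channel list was 5.03 in melanoma replicate 3 against 6.25 to 7.10 in the other melanoma libraries, and 5.24 and 5.68 in breast replicates 18 and 19 against 6.00 to 6.59 in the other breast libraries. Without these 3 libraries the 4 calls had camera adjusted p of 0.00254, 0.00916, 0.0125 and 0.00407. Of the melanocyte lineage genes 13 of 13 rose (13 adjusted over the list alone, camera adjusted p = 4.62e-24, adjusted p = 0.0705 with an estimated correlation). Pmel had a log2 fold change of 10.81. Of the epithelial genes 4 of 9 fell (4 adjusted over the list alone, camera adjusted p = 0.0185, adjusted p = 0.670 with an estimated correlation). Krt8 had a log2 fold change of -6.85 and Krt18, which did not pass, of -0.21. Of the sex-linked genes 4 of 5 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 1.99e-07, adjusted p = 0.0642 with an estimated correlation). Ddx3y was at least 1200-fold higher in melanoma and Xist lower (-9.45). With the 4 genes unread in breast at their bounds the median of this list was 8.70 in place of 10.8. Rhox2d, a reproductive homeobox gene, had no read in the melanoma libraries and was at least 393-fold lower than in breast. Fos was lower (-1.03, adjusted p = 0.00586), and Egr1 (0.12), Arc (-0.32), Nkx2-1 (0.39) and Sftpc (0.62) did not pass.

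In this comparison 4966 genes changed, 1676 higher and 3290 lower in melanoma, 2364 by over 2-fold, and 2933 (17.1%) showed no overlap (0.216% by chance). Without the 3 libraries poor in long transcripts 5955 changed, 4580 of the 4966 among them, and without melanoma replicate 3 alone 8078 changed, 4020 (49.8%) of them higher against 33.7% with it. Camera passed 22 of 48 lists (22 without the 3 libraries), 18 of which, all but the 4 neuronal lists, also passed the exact permutation test, none with an estimated correlation (10 under an unadjusted p of 0.05), and fry passed 25. Of 640 X-linked genes 31.7% changed, against 28.9% of all genes, and sex was again confounded with the model. The haemoglobin call ended without the 3 libraries (camera adjusted p = 0.0770), and the glutamate and GABA receptor calls once the trend with transcript length was removed (0.0813 and 0.0735). With the cell cycle covariate the epithelial, glutamate receptor, GABA receptor and MHC class II calls ended (0.0511, 0.0511, 0.0672 and 0.0531). With 1 library left out in turn, the ion channel call ended in 3 of 18 fits (range of adjusted p 6.77e-05 to 0.0826), the glutamate receptor call in 4 (0.000882 to 0.1), the GABA receptor call in 6 (0.012 to 0.112) and the vesicle release call in 2 (0.000648 to 0.061).

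Genes that differed the same way from both other models set each model apart. Whether the tumour cells or the tissue around them made the RNA of these genes was not tested. Epha2, an ephrin receptor tyrosine kinase, was low in the melanoma model, with 2.02 ± 0.586 in melanoma, 70.9 ± 15 in lung and 74.5 ± 15 CPM in breast (larger adjusted p = 1.27e-11). Bmp2, a bone morphogenetic protein, was high in the lung model, with 3.95 ± 1.10 in melanoma, 93.2 ± 16.5 in lung and 4.48 ± 0.551 CPM in breast (larger adjusted p = 8.62e-12). So were Cdkn2a, the locus of the p16 and p19 tumour suppressors (log2 fold changes 9.80 and 8.01), and Aqp5, an epithelial water channel (8.64 and 8.81). Ets1, a transcription factor of endothelium and lymphocytes, was low in the lung model, with 117 ± 46.7 in melanoma, 28.7 ± 3.46 in lung and 145 ± 30.8 CPM in breast (larger adjusted p = 1.46e-06). Dusp9, a MAP kinase phosphatase, was high in the breast model, with 0.928 ± 0.215 in melanoma, 3.37 ± 1.27 in lung and 66.2 ± 8.17 CPM in breast (larger adjusted p = 6.66e-11). St14, the epithelial protease matriptase, was high there too (4.64 and 6.36). Mlph, a melanosome transport adaptor, was low there, with 89.6 ± 49.3 in melanoma, 69.9 ± 15.4 in lung and 2.23 ± 0.394 CPM in breast. In total 2593 genes were set apart in melanoma (838 higher, 1755 lower), 1057 in lung (722 higher, 335 lower) and 1636 in breast (1338 higher, 298 lower). Without the 3 libraries poor in long transcripts these were 3165 (1166 higher, 1999 lower), 1642 (1168 higher, 474 lower) and 2068 (1349 higher, 719 lower). Without melanoma replicate 3 alone, 786 genes were lower in breast in place of 298. The 2 contrasts behind each count share 6 libraries. No gene was called in 10 simulations of unchanged models. These drew each gene independently, so they cannot bound chance in libraries whose genes vary together. Independent lists of the same sizes would share 625, 343 and 488 genes. With the shared libraries halved, 3 for each contrast, the medians over 20 halvings were 1870.5 (1782 to 2230), 636 (623 to 716) and 1017 (798 to 1142), beside 389, 147 and 247 for independent lists.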

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

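All tests in this part were chosen after the results had been seen. A library was picked out when its gap to the next library of its model was large for 6 values. Of 378 groups of 6 tested 30 passed, where 18.9 (about 1 in 20) would pass if the groups were independent and their values normal. Genes were tested as CPM without logs, and the groups share libraries and, for lists, genes. The 18.9 is thus no exact expectation by chance. The value given for each is the gap as a share of the range of the 6 (gap share).

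In melanoma replicate 1 the gap share was 0.896 for the MHC class II list (mean log2 CPM 6.36, others 1.45 to 1.96), 0.858 for T and NK cell genes, 0.74 for complement, 0.731 for MHC class I, 0.73 for dendritic cell, 0.676 for lung epithelium and 0.633 for interferon gamma response genes. By gene it was 0.921 for Pdcd1, 0.907 for H2-D1 (603 CPM, others 61.6 to 112), 0.867 for H2-K1, 0.785 for Rsad2, 0.783 for Arg1, 0.69 for C1qc and 0.628 for Lck. Melanoma replicate 3 was lowest in its slope with transcript length (0.697) and in the meninges list (0.668), and highest in Tyr (0.71, 548 CPM, others 66.0 to 206) and Nfkbia (0.767). Melanoma replicate 4 was highest in Fos (0.733, 25.2 CPM, others 7.83 to 12.5) and Arc (0.734, 165 CPM, others 16.2 to 55.8). Lung replicate 8 was highest in the cerebellum list (0.636), lung replicate 7 in Csf3r (0.655) and lung replicate 10 in Syn2 (0.718). Breast replicate 14 was highest in Arg1 (0.914, 70.6 CPM, others 9.43 to 14.7), Acan (0.695) and Mlph (0.722), breast replicate 17 in Col6a1 (0.714), and breast replicate 19 in Sftpc (0.636) and Gabra5 (0.66), while breast replicate 18 was lowest in Syn2 (0.672).

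Immune and reactive astrocyte genes were lower around melanoma. Of 166 such genes 109 fell against lung (3 rose, median log2 fold change -1.88) and 132 against breast (2 rose, median -2.42). The 166 were the tested members of lists that camera had already called lower in both comparisons of melanoma. Their counts and medians thus restate those calls and are no further test. The B cell and dendritic cell lists, not called against lung, were left out. Dilution of brain RNA by tumour RNA would lower other brain genes alike, but 64 markers of neurons, astrocytes and oligodendrocytes had medians of -0.069 and 0.0843. RNA quality of 3 libraries does not account for it either, since 95 of 103 genes lower against both models (92.2%) stayed so without them, and neither does host sex against lung, since all 12 melanoma and lung libraries held Ddx3y reads (sex and model could not be separated against breast). Within the melanoma model the reactive astrocyte list had means of 4.08 to 4.23 in replicates 1 to 3. They were 3.46 to 3.75 in replicates 4 to 6, where melanocyte genes took fewer reads and the slope with transcript length was higher (0.234 to 0.243). The homeostatic microglia list did not share this, with 4.27 to 4.90 and 4.80 to 5.23. Whether the lung and breast tumour cells themselves made part of the immune and reactive astrocyte RNA was not tested, so the explanation stays open. A weaker glial and immune response around this melanoma line is a hypothesis that RNA of the cell lines grown alone and a tumour-free brain could test.

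Melanoma replicate 1 held more antigen-presentation RNA than the other 5 melanoma libraries, with H2-K1 at 235 CPM against a median of 38.4. Carry-over from a lung or breast library would need 24.9% or 21.3% of such a library, whereas marker genes of those models were in excess by at most 0.546% of their own level. The level of these markers was looked at first (at most 3.63%), and the measure was changed to the excess over the other melanoma libraries after that level had been seen. Depth and RNA quality do not account for it, with 13396710 counts and a slope with transcript length of 0.0585. No biological explanation was tested, as the design gives none.

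Whether chance could give such counts was tested by 60 groupings of the libraries, the real one and 59 drawn at random between the models compared. The real grouping alone gave as many genes (1 of 60) for melanoma against lung (3978, highest other 1987), breast against lung (3149, highest other 1), melanoma against breast (4966, highest other 1382), any difference (6146, highest other 0) and the genes set apart (2593, 1057 and 1636, highest other 0 each). As 1 of 60 is the smallest share that 60 groupings can give, chance is bounded only to that level. Random groupings also mix the models, which widens the spread within groups and lowers their counts. The number of called lists did not stand out from the random groupings. Of 60 groupings 33, 33 and 12 called as many as the real 18, 13 and 22 (highest other 30, 27 and 28).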

How the results depend on the processing

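Alternatives were fixed before the data were examined, except those without the 3 libraries poor in long transcripts, with the length trend removed, with reads recovered from CPM and with exact permutation of list means, which were chosen after results had been seen. No paired analysis was possible because the library numbers run on across the models and no number is shared. A sex covariate was not run, as it is constant within each model. With 1 library left out, changed genes ran from 3495 to 4623 (melanoma against lung), 2575 to 4113 (breast against lung) and 4520 to 8078 (melanoma against breast), set-apart genes from 2294 to 3178, 914 to 1216 and 1317 to 2433, genes differing at all from 5653 to 8720, and called lists from 18 to 20, 11 to 15 and 18 to 24. The highest gene counts came without melanoma replicate 3. Testing against 1.5-fold left 1897, 1053 and 2218 changed genes and 1270, 420 and 511 set apart, by its construction. Genes set apart in lung were 1643 with 1 surrogate variable and 1642 without the 3 libraries poor in long transcripts, and the cause was not tested. With an estimated correlation 0, 0 and 0 lists were called. The estimates lay far above the preset 0.01 for many lists. They were 0.950 for MHC class II, 0.936 for MHC class I, 0.889 for type I interferon and 0.130 for fibroblast and collagen matrix genes. Camera with the preset correlation thus understates the variance of such lists, and its p values for them are too small. The vesicle release list, breast against lung, turned direction with the cell cycle covariate (adjusted p = 0.647), and the cause was not tested. The covariate itself did not overlap between the breast and lung libraries. DESeq2 called 4943, 3971 and 6055 genes, limma voom 3979, 3247 and 5052, limma on the deposited CPM 3603, 2945 and 4604, and fits of 12 libraries 3413, 4127 and 4043, where breast against lung had the most. Of 53 called lists 47 stayed without the 3 libraries, 49 with the length trend removed, 43 by fry, 38 by exact permutation and 53 under library totals, the stricter filter or a prior count of 0.5, and 39 of 51 with the cell cycle covariate. Of 217 called genes named or members in their comparisons 190 kept their call in every alternative in which they were tested (33 at most, as the deposited CPM and the stricter filter hold fewer genes), 18 lost it in an alternative other than the 1.5-fold test and 0 turned direction. Sftpc, not called, passed with the length trend removed (adjusted p = 0.0338 in melanoma against lung and 0.0314 in melanoma against breast), and without melanoma replicate 4 (0.0414) or lung replicate 11 (0.0488) in the first and without breast replicate 19 (0.0343) in the second. Hbb-bs, Lck and Syn2 (breast against lung) and Snap25 (melanoma against breast) were among those that lost it when a single library was left out, with adjusted p up to 0.0826, 0.0583, 0.0525 and 0.0702. The share of higher genes in breast against lung was 61.0%, 46.8% without the 3 libraries and 48.3% with the cell cycle covariate. Depth put the floor of 3 counts at up to 0.419 CPM, in breast replicate 18.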

Other observations

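The genes of this part were chosen after their values had been seen. The hypoxia list was not called (camera adjusted p = 0.536, 0.0642 and 0.544 for melanoma against lung, breast against lung and melanoma against breast, adjusted p = 0.913, 0.774 and 0.913 with an estimated correlation), and of its 11 members 2 rose and 1 fell, 4 rose and 2 fell, and 3 rose and 5 fell. By exact permutation and fry it passed as higher in breast against lung (0.00725 and 0.00239) and lower in melanoma against breast (0.0133 and 0.0111), and not in melanoma against lung (0.427 and 0.599). Adm, the vasodilator adrenomedullin, had log2 fold changes of -0.94, 2.66 and -3.60, Egln3, an oxygen-sensing hydroxylase, -0.28 (not past the test), 2.36 and -2.64, and Car9, a carbonic anhydrase, 2.35, 0.26 (not past) and 2.09. The activated endothelium list was not called either (camera adjusted p = 0.0873, 0.815 and 0.279, adjusted p = 0.498, 0.945 and 0.778 with an estimated correlation). By exact permutation it passed as lower in all 3 (adjusted p = 0.00725, 0.0133 and 0.00725), and by fry in the comparisons of melanoma (1.285e-06 and 4.89e-06, against 0.63 in breast against lung). In breast against lung its median log2 fold change was 0.0253 and its mean -0.372, so that these differ in sign. Of its 8 members 0 rose and 4 fell, 2 rose and 3 fell, and 1 rose and 2 fell. Log2 fold changes were, for Sele, E-selectin, -2.29, 3.64 and -5.93, for Selp, P-selectin, -5.83, -2.85 and -2.98, and for Esm1, a marker of endothelial tip cells, -2.30, -4.45 and 2.15.

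Immediate early genes were not called as a list (camera adjusted p = 0.0693, 0.274 and 0.467, adjusted p = 0.873, 0.897 and 0.924 with an estimated correlation). By fry they passed as lower in melanoma against lung (adjusted p = 0.0218, then 0.444 and 0.136), and by exact permutation in none (0.0980, 0.381 and 0.381). Of 16 members 6 fell and 1 rose in melanoma against lung, 0 changed in breast against lung, and 5 fell and 1 rose in melanoma against breast. Among those that fell around melanoma was Junb, an AP-1 subunit (-2.67 against lung, -2.21 against breast), and the only one that rose was Nr4a3, an orphan nuclear receptor (2.06 and 2.02). In the lung model replicates 8 and 10 were below the other 4 in the interferon gamma response list (3.03 and 3.02 against 5.91 to 7.26).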
